A study of Mus musculus with 16 samples.

How the data were processed

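Single-cell RNA-seq libraries (10x Genomics, version 3 chemistry, from a FACS-sorted mixture of an epithelial fraction and a digested lamina propria fraction) were measured in the transverse colon of 16 mice. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 and counted with Cell Ranger 3.0.2. The deposited matrix held 16039 genes in 22717 cells, and a deposited annotation gave each cell a mouse, a group, a tissue layer and 1 of 46 cell types. The deposited values of the authors were in the unit log2: the UMI count of a gene divided by a size factor of the cell, plus 1, on the log2 scale. This was tested on the values themselves. Undoing the logarithm gave whole multiples of 1 step per cell for 100% of 60867816 entries above 0 (tolerance 1e-06, largest deviation 5.3e-10). The columns of the deposited annotation were in the unit other, as text labels of the authors. The authors' size factor method, filters on cells and treatment of doublets were not stated. Cells held 996 to 59845 UMIs (median 8849) and 498 to 6481 genes, with at most 50.1% mitochondrial UMIs. The annotation named the treated group SWAP, which was taken as SZN-1326-p from the sample names.

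Groups were the arm and time of each mouse, and each mouse was 1 replicate: 2 uninjured, 3 anti-GFP and 3 SZN-1326-p mice at 24 h and the same at 48 h. Replicate numbers were not used as pairs. Cell types were gathered into epithelial, progenitor, fibroblast, endothelial, T lymphoid, B or plasma, and myeloid classes. The comparisons, the gene lists (29), the rule for naming genes and the first set of alternative settings were fixed before the data were examined. The planned test on raw counts was replaced, since the deposited unit is log2, so that the main test of genes was chosen after the unit was known.

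For each mouse and class with at least 20 cells, the un-logged normalized UMIs were averaged over cells, and log2 of this mean plus 0.01 was tested. A gene was kept with a mean of at least 0.05 normalized UMIs per cell in at least 2 mice. The test was limma 3.58.1 (trend, robust) in R 4.3.3, with all 16 mice in 1 fit of the 6 groups (10 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. Contrasts were SZN-1326-p against anti-GFP at 24 h, at 48 h, their mean and their difference, and anti-GFP against uninjured over both times. Log2 changes carry their standard errors, and levels carry the SD over mice. Adjusted p values of genes come from limma, and those of lists from limma's camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were run beside it. Gene models, ribosomal protein, mitochondrial, immunoglobulin and haemoglobin genes were counted but not named. Up to 10 genes in each direction were named by size of change among those past the test, with at least 20 CPM (UMIs scaled to a common total) and all mice on the same side of the other group's mean. A fixed set of Wnt, cell cycle and epithelial genes was set for naming whatever its result, with up to 4 members of each list past its test. Not every one of these genes is printed below for every comparison.

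Shares of cell types within their compartment were compared as log2 of the share, with 0.5 cell added to each count, by two-sided exact permutation within each time, in Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6. This gives a smallest p of 0.005 for SZN-1326-p and 0.01 for DSS. Limits for a count of 0 use 3 cells and cover counting error only. Coordinates are from GENCODE vM21 (mm10), in which 15876 of the 16039 symbols were found once.

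On simulated data for SZN-1326-p at 48 h, the gene test recovered 5.97% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 92.4% of those changed 4-fold in epithelial cells, with 4.76% false calls. In progenitors it recovered 28.4% at 2-fold and 89.4% at 4-fold. In this simulation genes varied independently of each other, with the same spread in every mouse. The measured libraries share structure across genes: at 24 h another split of the same 6 mice called 2388 epithelial genes. These rates of recovery and of false calls therefore do not carry over to the measured data. The share test called 7% of unchanged, 82% of 2-fold and 100% of 4-fold types at an unadjusted p of 0.05. These simulated types had a single mean share and compartment size. Their spread between mice was smaller than in measured types such as TA1 (9.94% ± 18.2 SD with SZN-1326-p). The rates therefore do not carry over to types that vary more, nor to adjusted p values.

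The alternative settings fixed at the start were no filter, a fit of the compared groups alone, replicate numbers as a block, each mouse left out in turn, no cells with 2 markers of another lineage, at least 50 cells per library, other list tests and other denominators of shares. Added after the data were seen were voom weights on recovered UMI sums, the mean of the deposited log2 values, median-of-ratios scaling, a pseudocount of 0.05, the omission of both SZN-1326-p mice with a high mitochondrial share, fixed weights for cell types with at least 5 cells per mouse, and a term for the 24 h libraries whose long-minus-short transcript difference in fibroblasts was above 0.2. Count models with other size factors were left out because the deposited unit is log2. Random draws of cells to an equal makeup were left out because too few types had 20 cells in every mouse.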

Results

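Single-cell RNA-seq was measured in the transverse colon of 16 female C57Bl/6J mice, 1 library per mouse. Colitis was induced in 12 mice with 4% dextran sulfate sodium (DSS), a polymer that injures the colon epithelium, in the drinking water. On day 4 these mice received 10 mg/kg of SZN-1326-p, a protein that activates Wnt signalling through chosen Frizzled (FZD) receptors, or of an anti-GFP control antibody. Tissue was taken 24 h later (day 5) or 48 h later (day 6), from 3 mice per treatment and time and from 2 uninjured mice at each time. The deposited table held 22717 cells, 936 to 2033 per mouse, with 9616512 to 21335421 UMIs per mouse and a median of 6459 to 11153.5 UMIs per cell. The authors' annotation placed 10373 cells in the epithelium, 7509 in the stroma and 4835 in the immune compartment, in 46 cell types.

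The libraries differed in measures that the labels do not give. The median mitochondrial share of UMIs was 18.9% in SZN-1326-p mouse 2 at 24 h and 24.1% in SZN-1326-p mouse 3 at 48 h, against at most 11.6% in the other DSS mice. It was 19.2% to 26.1% in the 4 uninjured mice, so that this measure also differed between the groups compared for DSS. Mice with a high mitochondrial share also held more epithelial cells. These were 56.8% to 73.3% of cells in uninjured mice, 58.4% and 54.9% in the 2 SZN-1326-p mice and at most 43.7% in the other DSS mice. RNA quality and cell makeup are therefore not told apart by this measure. At 24 h, 4 libraries (uninjured mouse 1, anti-GFP mice 1 and 2, SZN-1326-p mouse 1) held more UMIs of long than of short transcripts, relative to the mean library. The long-minus-short difference in fibroblasts was 0.26 to 0.55 log2 in these 4 and at most 0.12 in the other 12. Counts of genes are therefore also given with a term for this library split, which was added after the data were seen. At 48 h the same difference separated the arms in epithelial cells, at -0.058 to 0.13 with anti-GFP and -0.40 to -0.18 with SZN-1326-p. The arms were also separated in T lymphoid and myeloid cells and, narrowly, in fibroblasts, while endothelial cells overlapped. The term marks libraries at 24 h alone, so it does not address this difference at 48 h.

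The first comparison asked what DSS injury did to the colon, with anti-GFP mice (n = 6) set against uninjured mice (n = 4). The absorptive types Enterocyte, ImmEntero1 and ImmEntero2 were nearly lost, while the type AltEnterocyte appeared. Inflammatory monocytes and neutrophils took larger shares of the immune compartment. Fibroblasts of the type BaseCryptFB1 were no longer found, while injury-associated fibroblasts were more frequent. Epithelial cells formed 65.0% ± 8.25 (SD, n = 4) of the cells of uninjured mice and 30.0% ± 10.4 (SD, n = 6) of those of anti-GFP mice, while immune cells went from 7.90% ± 1.07 to 36.2% ± 9.95. Both shifts had p = 0.01 in a two-sided exact permutation test within each time (100 arrangements), the smallest p that this design can give.

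Among the 17 epithelial types, shares of the epithelium were lower for Enterocyte (19.6% ± 4.23 to 0.124% ± 0.196), ImmEntero1 (9.22% to 0.0807%) and ImmEntero2 (17.4% to 0.219%), the authors' names for mature and immature absorptive cells. Shares were higher for AltEnteroPC (2.68% ± 2.08 to 19.5% ± 4.12) and AltEnterocyte (to 11.7% ± 6.11), named as alternative progenitors and enterocytes. No AltEnterocyte cell was found among 4049 uninjured epithelial cells, which allows a share of up to 0.0741%. Each of these 5 had an adjusted p of 0.034 in the exact permutation test. Colonocyte markers were the highest-scoring marker set in AltEnterocyte (mean log2 5.65 relative to all types), as in Enterocyte (5.87). The same set led in AltEnterocyte2 (2.72% to 8.99%) and AltEnterocyte3 (1.87% to 3.99%), whose shares did not pass. The loss therefore covers the named types and not all absorptive cells. In the immune compartment, InjuryMono1 (0.205% to 18.9%), InjuryMono2 (5.39% to 26.9%) and ActNeutrophil (0.575% to 13.7%) took larger shares, while Macrophage (35.7% to 9.47%) and Plasma_IgA (28.3% to 1.78%) took smaller ones, each with an adjusted p of 0.0183. As a share of all cells, the Macrophage change turned to a log2 difference of 0.17. In the stroma, BaseCryptFB1 went from 42.9% ± 2.51 to 0 of 2256 cells, which allows up to 0.133%. InjuryCryptFB1 (0.0735% to 8.39%) and InjuryCryptFB2 (1.69% to 19.3%) were higher, and these stromal shifts had an adjusted p of 0.036. BaseCryptFB2, the other crypt-base type, stood at 10.5% and 9.72% (permutation p = 0.76).

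**Figure D1:**
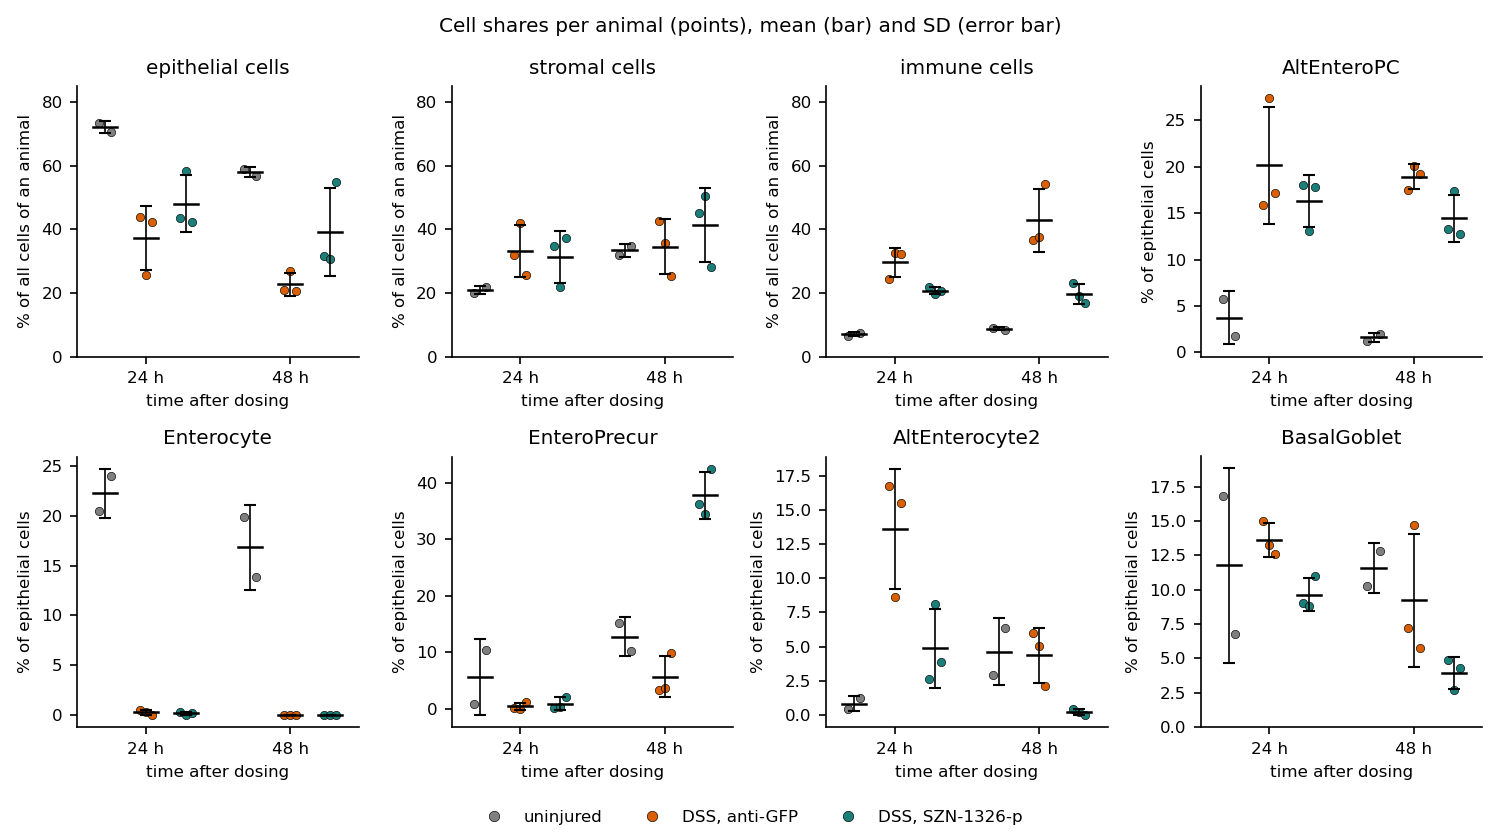
Shares of the 3 compartments and of single cell types in each mouse, in percent of all cells or of the compartment's cells, by group and time. Points are mice, horizontal bars are group means and error bars are 1 SD; over both times epithelial cells average 65.0% in uninjured, 30.0% in anti-GFP and 43.6% in SZN-1326-p mice.

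In epithelial cells as a whole, 6 of 13 antimicrobial genes rose and 1 fell with DSS (9 and 1 adjusted over the list alone), 11 of 25 NF-kB and cytokine genes rose, and 17 of 36 colonocyte and 16 of 27 oxidative phosphorylation genes fell. With a correlation estimated per list, 0 lists passed. Reg3b, an antimicrobial lectin, rose from 0.863 ± 1.17 to 66.1 ± 46.1 normalized UMIs per cell (SD; log2 7.53 ± 1.06 SE, adjusted p = 0.000806). Reg3g, of the same family, rose by 6.24 log2 (adjusted p = 0.000153) and the nitric oxide synthase Nos2 by 4.29 (adjusted p = 0.000404). Fabp2, which binds fatty acids in absorptive cells, fell from 22.2 ± 7.09 to 3.43 ± 0.624 (log2 -2.66, adjusted p = 2.72e-06). The Wnt feedback gene Axin2 fell from 0.183 ± 0.0386 to 0.0495 ± 0.0319 (log2 -1.92 ± 0.33, adjusted p = 0.000652). Ccnd1, a G1 cyclin, rose by 1.63 (adjusted p = 1.37e-05), and Ly6a, a marker of injured epithelium, by 2.26 (adjusted p = 3.57e-06). All 6 anti-GFP mice showed the direction of each of these 7 changes. Lgr5 (-0.60, adjusted p = 0.289), Myc (0.36, adjusted p = 0.254), Mki67 (0.86, adjusted p = 0.0896) and Muc2 (0.34, adjusted p = 0.553) did not pass. Reg3b lies at 78370657 to 78373466 on chromosome 6 and Fabp2 at 122895072 to 122899506 on chromosome 3.

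By list, 15 of 25 interferon response genes rose and 1 fell in DSS epithelium (19 and 1 adjusted over the list alone; adjusted p = 1.27e-08, adjusted p = 0.432 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 2.20 and Psmb8, an immunoproteasome subunit, by 1.64. For NF-kB and inflammatory cytokines 11 of 25 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 7.23e-05, adjusted p = 0.432 with an estimated correlation), among them Tnf by 2.15 and Duoxa2, a maturation factor of an oxidase, by 2.52. Of 27 oxidative phosphorylation genes 16 fell (21 adjusted over the list alone; median -0.62; adjusted p = 9.78e-08, adjusted p = 0.5 with an estimated correlation). Of 36 colonocyte genes 17 fell (19 adjusted over the list alone; median -0.54; adjusted p = 3.99e-07, adjusted p = 0.432 with an estimated correlation), with Selenbp1 at -1.96. All 12 tuft genes were measured and 7 rose (10 adjusted over the list alone; adjusted p = 7.23e-05, adjusted p = 0.432 with an estimated correlation). Neutrophil and monocyte genes, markers of cells outside the epithelium, moved with these groups, with 3 of 10 higher (8 adjusted over the list alone) and a median of 2.73 (adjusted p = 0.000988, adjusted p = 0.479 with an estimated correlation).

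Over both times limma called 2510 of 10795 genes in DSS epithelium, 1162 higher and 1348 lower (3644 with the library term), and camera called 14 lists, against up to 20 in other splits of these mice. The count was 1193 without uninjured mouse 2 at 24 h, and 1028 without uninjured mouse 1 at 48 h. A fit of these 10 mice alone gave 2164, and 569 when 5 cell types were given fixed weights and the others left out. With those weights the colonocyte genes Krt20 (-1.36, adjusted p = 0.000146) and Slc26a3 (-1.47, adjusted p = 0.000444) and the membrane lipid-raft gene Mal (-2.51, adjusted p = 3.23e-05) turned to 1.10, 0.77 and 1.79. The 5 types were TA1, AltEnteroPC, BasalGoblet, Goblet1 and Tuft, so that these values are measured without any mature or immature enterocyte type.

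The second comparison asked which cells differed after SZN-1326-p, with 6 SZN-1326-p mice set against 6 anti-GFP mice within each time. Epithelial cells were more frequent and immune cells less frequent, and within the epithelium the types AltEnterocyte2 and BasalGoblet were rarer. Epithelial cells formed 43.6% ± 11.5 (SD, n = 6) of cells with SZN-1326-p against 30.0% ± 10.4 with anti-GFP, 1.48-fold more (exact permutation, two-sided, 400 arrangements, p = 0.025). Immune cells formed 20.2% ± 2.22 against 36.2% ± 9.95, a ratio of 0.571 (p = 0.005 in the same exact test, the smallest it can give). Stromal cells formed 36.2% ± 10.6 against 33.8% ± 7.58 (permutation p = 0.74). Dissociation and sorting also set the ratio between compartments. Both SZN-1326-p mice with a high mitochondrial share held the highest epithelial shares of their arm (58.4% and 54.9%), and without them the epithelial shift did not pass (log2 0.56 to 0.35, permutation p = 0.09), nor did it without any one of 4 mice (SZN-1326-p 2 at 24 h, SZN-1326-p 3 and anti-GFP 1 and 3 at 48 h; permutation p = 0.055 each). The immune shift passed in each of these settings (log2 -0.74 without both mice, permutation p = 0.01). With replicate numbers as a block the epithelial shift kept its size but did not pass.

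AltEnterocyte2 made up 2.54% ± 3.14 of epithelial cells with SZN-1326-p and 8.99% ± 5.93 with anti-GFP (log2 -3.01), and BasalGoblet 6.79% ± 3.28 against 11.4% ± 3.96 (log2 -0.83). Each had an exact permutation p of 0.005 and an adjusted p of 0.0425 over the 17 epithelial types. The pooled progenitors (stem and transit-amplifying types) formed 39.7% against 28.1% (permutation p = 0.02, tested on its own), with 45.7% against 26.6% at 24 h and 33.6% against 29.6% at 48 h (permutation p = 0.1 and 0.4, where 0.1 is the smallest p of 3 mice against 3). EnteroPrecur, the precursor of enterocytes, had 832 cells among 4381 with SZN-1326-p and 45 among 1943 with anti-GFP, with a mean share of 19.3% ± 20.3 against 3.08% ± 3.69, which did not pass adjustment (permutation p = 0.045, adjusted p = 0.128). Of its 832 cells 814 came from 48 h, where its share was 37.7% ± 4.16 against 5.69% ± 3.65 (7.19-fold, 3 of 3 mice higher, permutation p = 0.1), while at 24 h it was 0.956% against 0.476%. Tuft (log2 -1.33, adjusted p = 0.128), AltEnterocyte (log2 -1.63, adjusted p = 0.085) and InjuryMono1 (log2 -0.88, adjusted p = 0.165) did not pass either. No immune or stromal type passed, and no type differed between the times (lowest adjusted p = 0.397). Neither epithelial call held with replicate numbers as a block, or when both SZN-1326-p mice with a high mitochondrial share were left out. Both settings leave fewer arrangements, so that 2 types alone could not pass adjustment there whatever their difference. Nor did either call hold without any one of 8 mice: anti-GFP 1, 2 and 3 and SZN-1326-p 1 at 24 h, anti-GFP 2 and SZN-1326-p 1, 2 and 3 at 48 h. The log2 difference of AltEnterocyte2 without one of these lay between -3.34 and -2.48, and that of BasalGoblet between -0.92 and -0.64.

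The third comparison asked what SZN-1326-p changed in epithelial cells 24 h after dosing, with 3 mice against 3. The Wnt feedback genes Axin2 and Rnf43 rose, as did 27 of 34 ribosome biogenesis, 26 of 35 DNA replication and 17 of 34 mitosis genes, and 10 of 36 colonocyte genes fell. With a correlation estimated per list, 1 list passed, that of ribosome biogenesis. Axin2, a direct Wnt target that restrains the pathway, rose from 0.0341 ± 0.0385 to 0.116 ± 0.0151 normalized UMIs per cell (SD, n = 3; log2 1.86 ± 0.41, adjusted p = 0.0119), against 0.182 ± 0.0658 in 2 uninjured mice. Slc11a2, an iron transporter, rose from 0.173 ± 0.0722 to 0.757 ± 0.3 (log2 2.07 ± 0.27, adjusted p = 0.00176), and Gpx2, an epithelial glutathione peroxidase, from 2.50 ± 0.764 to 7.66 ± 1.81 (log2 1.62 ± 0.25, adjusted p = 0.00209). Krt20, a keratin of mature surface cells, fell from 4.63 ± 1.15 to 1.78 ± 0.415 (log2 -1.37, adjusted p = 0.00554). All 3 treated mice showed the direction of each of these changes.

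Of 14 measured Wnt target genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.32, adjusted p = 0.0012, adjusted p = 0.539 with an estimated correlation). These were Axin2, Rnf43, a ligase that removes Frizzled receptors (1.13, adjusted p = 0.0102), Myc (1.45, adjusted p = 0.00649), Ccnd1 (0.78, adjusted p = 0.0402) and Cdca7 (1.07, adjusted p = 0.0141). Lgr5, the stem cell receptor, stood at 0.33 (adjusted p = 0.702) and Znrf3 at 0.22 (adjusted p = 0.678), and Nkd1, Notum and Ascl2 were below the filter. Among 11 Wnt receptors and co-receptors 1 fell, Fzd5, from 1.28 ± 0.156 to 0.785 ± 0.104 (log2 -0.70 ± 0.17, adjusted p = 0.017), and the list did not pass (adjusted p = 0.772). In coordinates, Axin2 lies at 108920349 to 108950783 on chromosome 11, Rnf43 at 87662722 to 87735539 on chromosome 11 and Fzd5 at 64730558 to 64737751 on chromosome 1.

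Of 34 ribosome biogenesis and Myc target genes 27 rose and 0 fell (32 adjusted over the list alone; median 0.97, adjusted p = 1.91e-24), and this call held with an estimated correlation (adjusted p = 0.0258). Nhp2, part of small nucleolar ribonucleoproteins, rose by 1.79 ± 0.25 (adjusted p = 0.00176), Gar1 of the same particle by 1.27 (adjusted p = 0.00182) and Ppan, a factor for large subunits, by 1.21 (adjusted p = 0.00176). Of 35 DNA replication genes 26 rose (30 adjusted over the list alone; median 1.08, adjusted p = 3.95e-22, adjusted p = 0.0974 with an estimated correlation), with Fen1, a flap endonuclease, at 1.42 and Tyms, thymidylate synthase, at 1.07. Of 34 mitosis genes 17 rose (29 adjusted over the list alone; median 0.93, adjusted p = 2.59e-16, adjusted p = 0.535 with an estimated correlation), with Cdk1 at 1.42 and Birc5, a chromosomal passenger protein, at 1.64. Mki67 (0.72, adjusted p = 0.316) and Top2a (0.89, adjusted p = 0.0639) did not pass, and with the library term stood at 1.13 (adjusted p = 0.011) and 1.14 (adjusted p = 0.00328). Of 36 colonocyte genes 10 fell (17 adjusted over the list alone; median -0.65, adjusted p = 1.32e-07, adjusted p = 0.535 with an estimated correlation), with Guca2a, the precursor of guanylin, at -1.46 (adjusted p = 0.011). Outside the list, Slc13a2, a citrate transporter, fell by 1.68 (adjusted p = 0.00371), Alpi, intestinal alkaline phosphatase, by 1.97 (adjusted p = 0.00649) and Bmp3 by 1.47 (adjusted p = 0.00176). Of 24 epithelial junction genes 2 fell (3 adjusted over the list alone; median -0.38, adjusted p = 0.00464, adjusted p = 0.535 with an estimated correlation). Of 27 oxidative phosphorylation genes 0 passed singly (0 adjusted over the list alone; median 0.29, adjusted p = 0.0213, adjusted p = 0.982 with an estimated correlation), and this list call was lost with the library term (adjusted p = 0.562).

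At 24 h limma called 1095 of 10795 genes, 636 higher and 459 lower, and 1694 with the library term, while a split of the same 6 mice by transcript length gave 2388. By camera 7 of 29 lists passed, and another split of the 6 mice gave 20. The count was 360 without both mice with a high mitochondrial share. In a fit of the 6 mice alone it was 0, and 1 with fixed weights for 9 cell types in those 6 mice, so that the fall from 1095 is not put down to the weights. Leaving out single mice gave 491, 275 and 1880 for anti-GFP 1, 2 and 3 and 1734, 459 and 311 for SZN-1326-p 1, 2 and 3. The calls of Axin2 and Rnf43 were lost without anti-GFP mouse 2 (log2 1.68, adjusted p = 0.0653; log2 1.00, adjusted p = 0.0581), that of Fzd5 without each of 4 mice (anti-GFP 1 and 2, SZN-1326-p 2 and 3; adjusted p = 0.0628 to 0.078), that of Cdca7 without anti-GFP 2 or SZN-1326-p 2 (adjusted p = 0.0736 and 0.0657), that of Guca2a without anti-GFP 2 (log2 -1.18) and that of Ccnd1 without any one of the 6.

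**Figure D2:**
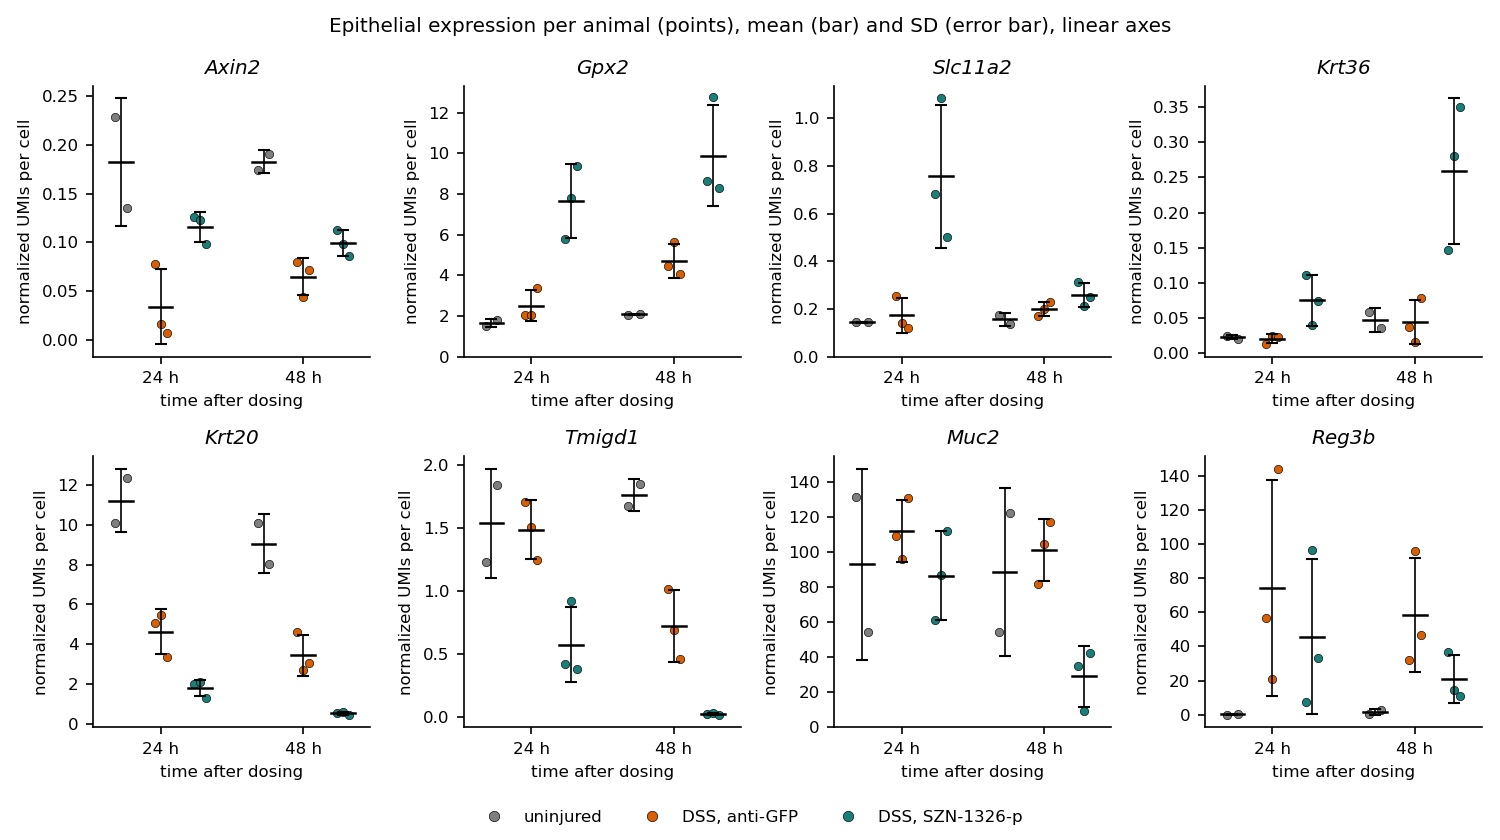
Mean normalized UMIs per epithelial cell of named genes in each mouse, by group and time, on linear axes that include 0. Points are mice, horizontal bars are group means and error bars are 1 SD; Axin2 at 24 h averages 0.182 in uninjured, 0.0341 in anti-GFP and 0.116 in SZN-1326-p mice.

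The fourth comparison asked the same at 48 h, again with 3 mice against 3. Of the lists, 22 of 36 colonocyte, 12 of 12 tuft and 6 of 23 goblet genes fell, and 12 of 34 mitosis genes rose. With a correlation estimated per list, 0 lists passed. Tmigd1, an epithelial adhesion protein, fell from 0.722 ± 0.283 to 0.0267 ± 0.00844 normalized UMIs per cell (SD, n = 3; log2 -4.27 ± 0.31, adjusted p = 1.56e-06). Krt20 fell from 3.44 ± 1.04 to 0.509 ± 0.0628 (log2 -2.70, adjusted p = 1.06e-05), against 9.06 ± 1.48 in 2 uninjured mice. The mucin Muc2 fell from 101.3 ± 17.9 to 29.0 ± 17.6 (log2 -2.06, adjusted p = 0.0118). Krt36, a hair-type keratin, rose from 0.0443 ± 0.0315 to 0.259 ± 0.104 (log2 2.39 ± 0.42, adjusted p = 0.0012), and Id1, a target of BMP signalling, from 1.68 ± 0.158 to 4.66 ± 0.923 (log2 1.45, adjusted p = 0.00216).

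Of 36 colonocyte genes 22 fell and 0 rose (24 and 1 adjusted over the list alone; median -1.25, adjusted p = 1.29e-11, adjusted p = 0.342 with an estimated correlation). Slc9a3, a sodium/proton exchanger, stood at -2.71 (adjusted p = 3.36e-05) and Guca2a at -2.68 (adjusted p = 6.29e-05), and the carbonic anhydrases Car4 and Car1 at -3.26 (adjusted p = 4.48e-05) and -1.93 (adjusted p = 0.0083). All 12 tuft genes fell (12 adjusted over the list alone; median -2.40, adjusted p = 1.29e-11, adjusted p = 0.342 with an estimated correlation), with the actin-binding Avil at -2.54 and Rgs13, a regulator of G-protein signalling, at -2.96. Tuft cells themselves formed 0.559% ± 0.195 of epithelial cells with SZN-1326-p (11 cells) and 3.64% ± 0.984 with anti-GFP at 48 h (0.166-fold, permutation p = 0.1). Of 23 goblet and secretory genes 6 fell (13 adjusted over the list alone; median -1.09, adjusted p = 1.8e-05, adjusted p = 0.659 with an estimated correlation), with Spdef, a goblet transcription factor, at -1.51 (adjusted p = 0.00316). Of 25 interferon genes 9 fell (13 adjusted over the list alone; adjusted p = 0.000174, adjusted p = 0.659 with an estimated correlation). Irf7, a transcription factor of that response, stood at -2.07 (adjusted p = 6.61e-05), and Stat2 at -1.15 (adjusted p = 0.000816) turned to 0.04 with fixed weights for cell types. RNA of leukocytes in these epithelial cells moved the same way: 1 of 10 neutrophil and monocyte genes fell (0 adjusted over the list alone; median -1.99), a list that did not pass (adjusted p = 0.0777). Cells with 2 markers of another lineage were 31 of 235, 20 of 319 and 27 of 192 with anti-GFP and 17 of 510, 16 of 449 and 17 of 1117 with SZN-1326-p, and without them Irf7 stood at -2.15 and Stat2 at -1.11, both past the test. Of 24 hypoxia and glycolysis genes 5 fell (10 adjusted over the list alone; adjusted p = 0.00697, adjusted p = 0.659 with an estimated correlation), with the collagen prolyl hydroxylase subunit P4ha1 at -1.45 (adjusted p = 7.61e-05).

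Of 34 mitosis genes 12 rose at 48 h (20 adjusted over the list alone; median 0.74, adjusted p = 1.42e-13, adjusted p = 0.55 with an estimated correlation), with the mitotic kinase Cdk1 at 1.04 (adjusted p = 0.0182). Of 34 ribosome biogenesis genes 4 rose (4 adjusted over the list alone; median 0.33, adjusted p = 1.36e-08, adjusted p = 0.342 with an estimated correlation), with the nucleolar chaperone Npm1 at 0.93 (adjusted p = 0.00675). The Wnt target list did not pass (adjusted p = 0.295), and its median of 0.09 and mean of -0.15 differed in sign. Axin2 measured 0.0993 ± 0.0131 against 0.0650 ± 0.0186 (log2 0.57, adjusted p = 0.394), and its effect was not shown to differ from that at 24 h (interaction adjusted p = 0.503). Rnf43 stood at 0.72 (adjusted p = 0.0608), Myc at 0.53 (adjusted p = 0.229), Lgr5 at -0.93 (adjusted p = 0.24) and Fzd5 at -0.13 (adjusted p = 0.671).

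At 48 h limma called 1345 of 10795 genes, 260 higher and 1085 lower, all 3 treated mice showing the direction of each gene named above as called, and 2556 with the library term. Depth differed between these arms: median UMIs per epithelial cell were 16330 to 17164 in anti-GFP mice and 9391 to 14646 in SZN-1326-p mice, without overlap. Values were scaled by the size factor of each cell, but depth was not varied, so its part in these calls was not tested. By camera 9 lists passed, and another split of the 6 mice gave 15. The count was 812 without both mice with a high mitochondrial share, 693 without anti-GFP mouse 1 and 590 without SZN-1326-p mouse 2, without which the call of Muc2 was lost (log2 -1.37). That of Car1 was lost without anti-GFP mouse 1 (log2 -1.59), and that of Cdk1 without anti-GFP mouse 1 or 3 (log2 0.95 and 0.80) or SZN-1326-p mouse 2 (log2 0.92). A fit of the 6 mice alone, with 4 residual degrees of freedom instead of 10, gave 1880, and 237 with fixed weights for 8 cell types. The long-minus-short transcript difference also separated the arms in epithelial cells at 48 h. The library term marks libraries at 24 h alone, so the part of that difference in these calls was not tested.

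**Figure D3:**
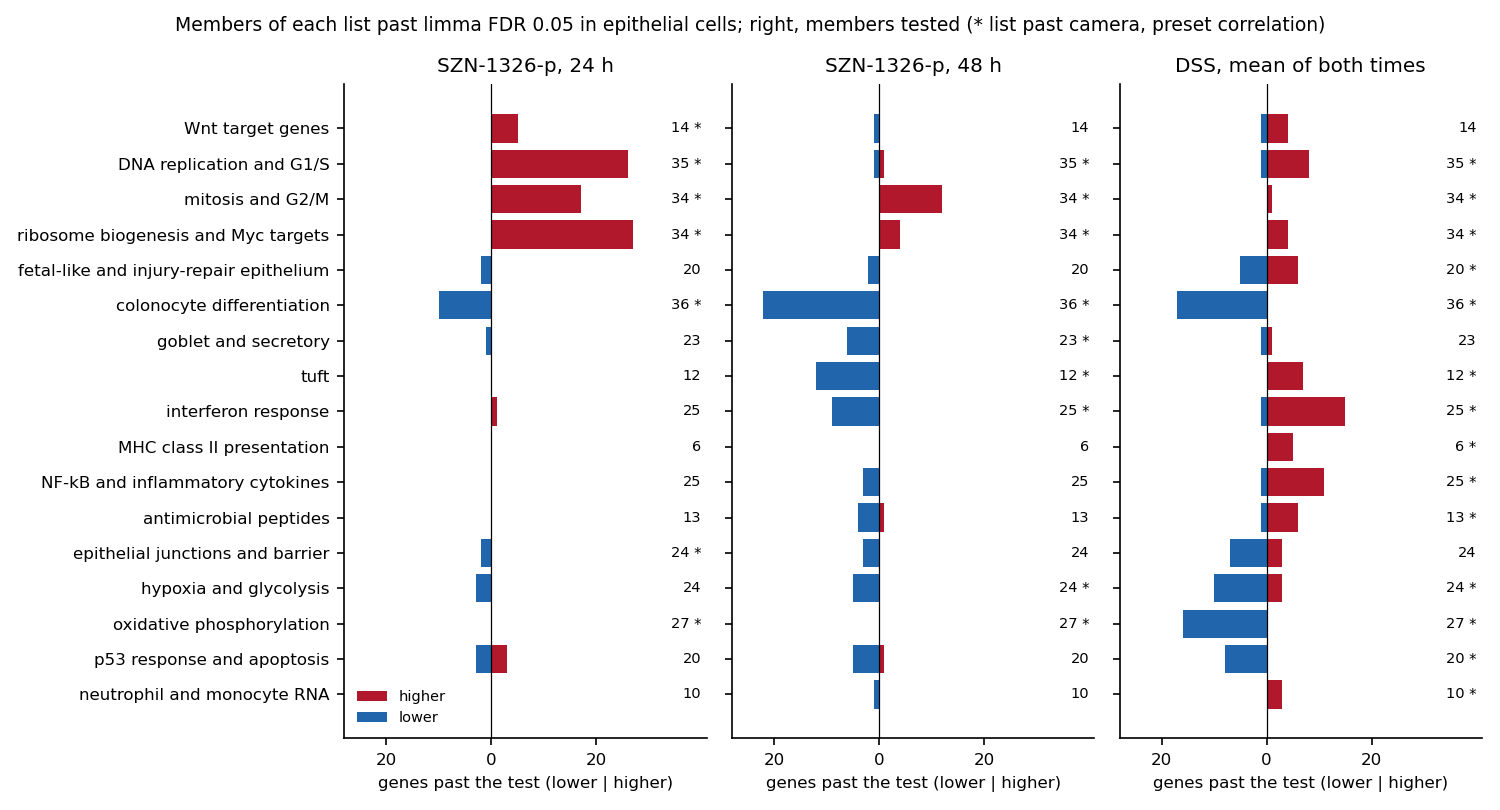
Number of genes of each list past limma at a false discovery rate of 0.05 in epithelial cells, higher to the right and lower to the left, for SZN-1326-p against anti-GFP at 24 h and at 48 h and for DSS (anti-GFP against uninjured, mean of both times). The number at the right of each panel is the count of genes tested, and a star marks a list past camera with its preset correlation; 27 of 34 ribosome biogenesis genes rose at 24 h and 12 of 12 tuft genes fell at 48 h.

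Over both times together, 6 SZN-1326-p mice against 6 anti-GFP mice, limma called 3038 of 10795 epithelial genes, 1177 higher and 1861 lower, and 3861 with the library term. A fit of these 12 mice alone gave 2774, and 228 with fixed weights for 4 cell types, which leave out the cells of every other type. The genes called lower at 24 h and at 48 h shared 259 members, against 46.1 for independent calls. Those called higher shared 89, against 15.3. These expected numbers treat genes as independent of each other, but the measured libraries share structure across genes. The overlaps are therefore no test against chance. Pearson's r between the effects at 24 h and at 48 h was 0.57, inside the central range of simulated unchanged groups (-0.711 to 0.659). In a test of the difference between times, 15 genes passed, 1 with a more positive and 14 with a more negative effect at 48 h. These held Tmigd1 (-2.81, adjusted p = 0.036), the interferon genes Irf7 (-1.95, adjusted p = 0.036) and Ifit2 (-3.52, adjusted p = 0.036), the tuft gene Avil (-2.72, adjusted p = 0.036), Srm, spermidine synthase (-1.43, adjusted p = 0.0483), and the heat shock gene Hspa1b (-2.98, adjusted p = 0.036). The count of 15 was 60 with the library term, 0 without both mice with a high mitochondrial share and 46 without cells that held markers of another lineage. It was 0 without anti-GFP 1, SZN-1326-p 1 or SZN-1326-p 2 at 24 h or without anti-GFP 1, SZN-1326-p 1 or SZN-1326-p 3 at 48 h, 1 without anti-GFP 2 at 24 h or anti-GFP 3 at 48 h, and 4 without SZN-1326-p 2 at 48 h.

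Wnt target levels were also compared within AltEnteroPC, the type with at least 20 cells in every DSS mouse, in 11 genes chosen after the data were seen, some of them already called in all epithelial cells of the same mice, so that the p values below describe these genes and are no independent test. Axin2 measured 0.0598 ± 0.0219 normalized UMIs per cell (SD, n = 6) with SZN-1326-p and 0.0065 ± 0.0092 with anti-GFP (log2 2.18, higher in 6 of 6 mice, exact permutation p = 0.005, adjusted p = 0.0138). Rnf43 measured 0.349 ± 0.105 against 0.119 ± 0.0427 (log2 1.48, exact permutation, adjusted p = 0.0138) and Gpx2 8.52 ± 2.38 against 3.77 ± 1.44 (log2 1.21, exact permutation, adjusted p = 0.0138). Myc (log2 1.73, adjusted p = 0.022) and Krt36 (log2 2.54, adjusted p = 0.0275) were also higher in 6 of 6 mice. Fzd5 measured 0.995 ± 0.122 against 1.72 ± 0.406 (log2 -0.75, exact permutation, adjusted p = 0.0138) and was lower in 6 of 6. Lrp6 (log2 -0.28, adjusted p = 0.196), Lrp5, Fzd7 and Fzd8 did not pass, and Lgr5 was 0 in both arms. In other types no test was run; in the mice with at least 20 of their cells mean Axin2 with SZN-1326-p and anti-GFP was 0.0903 and 0.0904 in BasalGoblet, 0.133 and 0.123 in TA1, 0.112 and 0.101 in TA2 and 0 and 0 in AltEnterocyte. It was 0.0804 and 0 in AltEnterocyte2. Rnf43 was 0.208 and 0.0768 in BasalGoblet, 0.339 and 0.0781 in AltEnterocyte, 0.331 and 0.288 in TA2 and 0.315 and 0.437 in TA1. In the type named StemCell, mean Axin2 was 0.463 ± 0.0458 in 4 uninjured mice and 0.277 ± 0.0784 in 5 SZN-1326-p mice, while the 2 anti-GFP mice with 20 or more of these cells had 0.

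**Figure D4:**
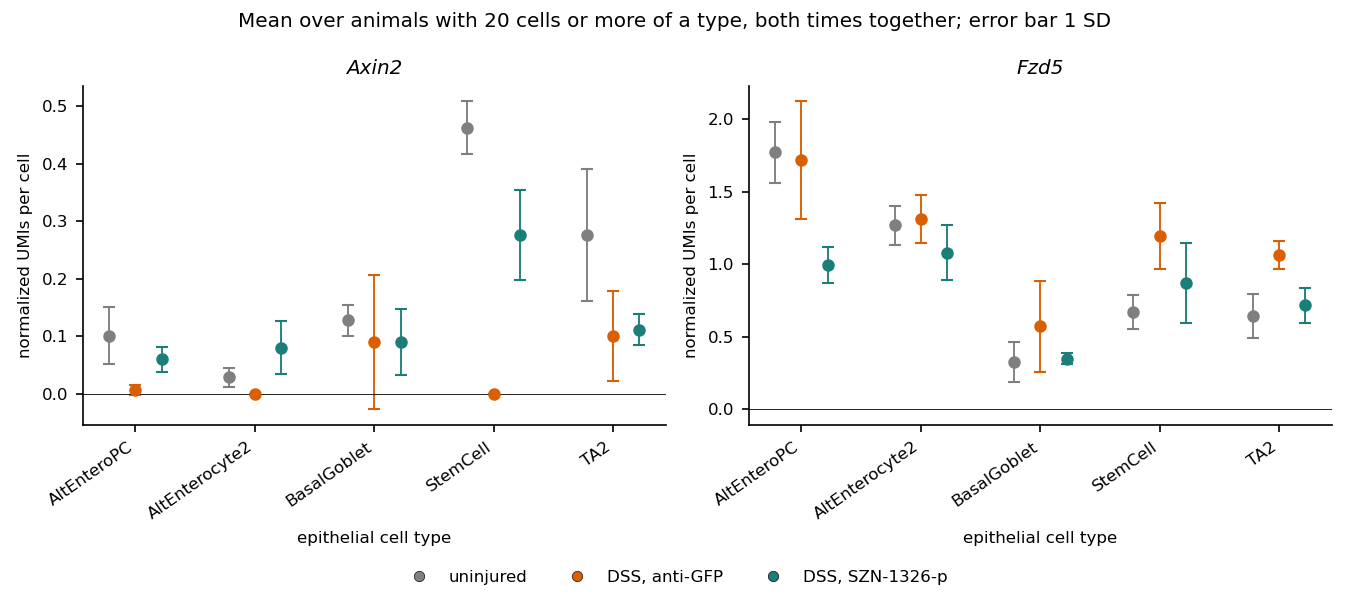
Normalized UMIs per cell of Axin2 and Fzd5 within single epithelial types, by treatment, both times together. Points are means over the mice with at least 20 cells of the type and error bars are 1 SD; Axin2 in AltEnteroPC averages 0.0598 with SZN-1326-p and 0.0065 with anti-GFP.

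The fifth comparison took the progenitors alone, the stem and transit-amplifying types, in which fewer genes passed than in all epithelial cells. The types in this class differed between arms: as shares of the epithelium with anti-GFP and SZN-1326-p, TA2 was 7.19% ± 10.97 and 24.9% ± 18.6, TA1 16.2% ± 13.0 and 17.6% ± 25.7 and StemCell 3.23% ± 4.76 and 3.25% ± 2.45 at 24 h. At 48 h they were 17.4% ± 6.03 and 20.5% ± 5.75, 5.90% ± 5.36 and 2.33% ± 0.236, and 6.295% ± 0.668 and 10.8% ± 0.367 (SD, n = 3). No fit with fixed weights was made for progenitors, so their changes are not separated from this makeup. At 24 h the genes that rose included Cdca8, a mitotic passenger protein (1.10, adjusted p = 0.0396), and those that fell Gsdmc3, a gasdermin (-1.53, adjusted p = 0.0396), and Hnf4g, a transcription factor of enterocytes (-1.07, adjusted p = 0.0484). At 48 h the cytokine Il18 rose from 0.301 ± 0.0552 to 1.27 ± 0.0702 normalized UMIs per cell (SD, n = 3; log2 2.06, adjusted p = 0.00243), and Ccnb1, a mitotic cyclin, rose by 1.16 (adjusted p = 0.0339). Cd44, a Wnt target and adhesion receptor, fell by 1.70 (adjusted p = 0.0329, and 0.0642 with the library term), the Wnt receptor Fzd7 by 1.54 (adjusted p = 0.0426) and Tgm2, a transglutaminase, by 2.02 (adjusted p = 0.0444). All 3 treated mice showed these directions, while Axin2 at 24 h (1.84, adjusted p = 0.137) did not pass. At 48 h progenitor means with SZN-1326-p and anti-GFP were 0.1575 and 0.1666 for Axin2, 0.0569 and 0.160 for Lgr5, 0.375 and 0.409 for Rnf43 and 0.0963 and 0.174 for Znrf3. They were 0.0664 and 0.0642 for Ascl2, and 0.0184 and 0.00105 for Nkd1.

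By list in progenitors at 24 h, 0 of 34 ribosome biogenesis genes passed singly (20 adjusted over the list alone), with a median of 0.63 (adjusted p = 1.99e-12, adjusted p = 0.528 with an estimated correlation). For 36 DNA replication genes the numbers were 0 and 6 adjusted over the list alone, with a median of 0.53 (adjusted p = 1.37e-09, adjusted p = 0.528 with an estimated correlation). At 48 h 2 of 35 mitosis genes rose (21 adjusted over the list alone; median 0.70, adjusted p = 5e-20, adjusted p = 0.324 with an estimated correlation). Genes of fibroblasts (median 0.89, adjusted p = 0.00201, adjusted p = 0.647 with an estimated correlation) and of neutrophils and monocytes (median -2.34, adjusted p = 0.0052, adjusted p = 0.647 with an estimated correlation) moved with the treatment at 48 h, with no single member past the test. Other splits of the 6 mice gave up to 15 lists at 24 h and 12 at 48 h, against 4 and 12 for the treatment.

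In progenitors limma called 12 of 10758 genes at 24 h and 36 at 48 h, 94 and 152 with the library term, and 0 at both times without the mice with a high mitochondrial share. At 24 h the count was 3, 0 and 394 without anti-GFP mouse 1, 2 or 3 and 629, 0 and 0 without SZN-1326-p mouse 1, 2 or 3, so that each gene named for 24 h lost its call without 4 of the 6 mice. At 48 h it was 19 without anti-GFP mouse 1, 9 without SZN-1326-p mouse 2 and 6 without SZN-1326-p mouse 3, and of the genes named Il18 alone passed without each of the 6. The difference between times gave 0 genes (694 at an unadjusted p under 0.05 in limma).

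The sixth comparison covered cells outside the epithelium, where few or no genes passed and most that did are transcripts of epithelial cells. In fibroblasts at 48 h, 10 genes were higher and 3 lower with SZN-1326-p. These included the gut hormones Gcg (3.26, adjusted p = 0.000376) and Pyy (4.14, adjusted p = 0.00382) and the epithelial Gpx2 (2.15, adjusted p = 0.00584), while the chaperone Hspa1b (-1.84, adjusted p = 0.0144) was lower. In the same fibroblasts the epithelial surface gene Epcam measured 62.0 ± 45.4 CPM with SZN-1326-p and 13.1 ± 8.05 with anti-GFP (SD, n = 3). In T lymphoid cells at 48 h Gcg (10.01, adjusted p = 1.13e-05), Insl5, another gut hormone (9.94, adjusted p = 1.13e-05), and Phgr1 (2.98, adjusted p = 0.00402) were higher, and 2 cells held 92.9% of the 336 Gcg UMIs. In myeloid cells Gcg (4.18, adjusted p = 0.0191) and the sulfotransferase Sult1a1 (1.95, adjusted p = 0.00892) were higher at 48 h, and in B or plasma cells Fabp2 (4.91, adjusted p = 0.0205).

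At 24 h limma called 0 genes in fibroblasts (769 at an unadjusted p under 0.05), endothelial cells (731), T lymphoid cells (797) and myeloid cells (508), and 0 in endothelial cells at 48 h (316). The count for fibroblasts at 48 h was 109 with the library term, 2 from voom weights on summed UMIs, and 8, 7 and 4 without anti-GFP 1, anti-GFP 2 or SZN-1326-p 3. It was 2 without both mice with a high mitochondrial share and 39 with a replicate block. For endothelial cells at 48 h it was 5 from voom and 3 without anti-GFP 1, anti-GFP 2 or SZN-1326-p 2. With at least 50 cells per library it was 22, and 2 with a replicate block or the library term. For T lymphoid cells at 48 h it was 6 without SZN-1326-p 1 or 2, and at 24 h 1 without anti-GFP 1 or SZN-1326-p 1. For myeloid cells at 48 h it was 32 from voom, 1 without anti-GFP 1, 21 without anti-GFP 3 and 0 without anti-GFP 2, SZN-1326-p 1 or SZN-1326-p 3, and at 24 h 1 without SZN-1326-p 1. At 48 h it was also 0 without both mice with a high mitochondrial share, 13 with a replicate block and 4 with at least 50 cells. For B or plasma cells it was 15 from voom, 6 without anti-GFP 3 and 0 without anti-GFP 1, anti-GFP 2 or SZN-1326-p 1.

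The last comparison asked whether SZN-1326-p moved epithelial genes against or along the DSS change. Across 10795 genes, which are not independent replicates, Pearson's r between the effects was -0.14 at 24 h and -0.28 at 48 h. Both effects use the same anti-GFP libraries, which alone gives a negative value, and unchanged groups in simulation gave a median r of -0.443 (central 95% -0.874 to 0.336) and -0.483 (central 95% -0.883 to 0.324). The measured r lay inside these limits and was less negative than the simulated medians at both times. Simulated covariances were -0.0416 and -0.045 against -0.0419 and -0.0988 measured. With DSS effects from the other time, which share no library, r was 0.07 for SZN-1326-p at 24 h and -0.18 at 48 h. Over the genes past the test for DSS alone these were 0.34 (561 genes) and -0.08 (1001 genes). Both lay inside the central 95% of unchanged groups (-0.6965 to 0.6251 and -0.6758 to 0.664). The effects at 24 h and at 48 h had an r of 0.57, inside the central 95% of unchanged groups (-0.711 to 0.659). Without anti-GFP mouse 3 or SZN-1326-p mouse 3 at 24 h, r at 24 h was -0.31 and -0.08.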

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

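The tests of makeup, of library preparation, of free RNA and of other cell types, and the term for the library split, were chosen after the results were seen, while the tests of other splits of the mice, of doublets and of what the library term does to the sizes of the changes were set before their results were seen.

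The effect of SZN-1326-p on 6 named epithelial genes differed between times in limma's interaction test, as log2 at 48 h minus 24 h. It was -2.72 for Avil, -1.95 for Irf7, -1.43 for P4ha1 and -2.81 for Tmigd1 (adjusted p = 0.036 each), -3.42 for Pik3r5 (adjusted p = 0.0485) and -1.43 for Srm (adjusted p = 0.0483). Medians of 7 epithelial lists also differed between times by camera: -0.72 for DNA replication, -0.80 for Wnt targets, -0.53 for colonocyte genes, -1.04 for goblet genes, -0.67 for interferon genes, -0.59 for ribosome biogenesis and -2.23 for tuft genes. With an estimated correlation the adjusted p of these 7 was 0.263 to 0.66. In progenitors 7 lists differed: -0.67 for DNA replication, 0.12 for colonocyte genes, -0.12 for dissociation genes, -0.83 for interferon genes, 0.20 for mitosis, -2.61 for neutrophil and monocyte genes and -0.74 for ribosome biogenesis. With an estimated correlation their adjusted p was 0.262 to 0.661. Other splits bear on the 15 genes that differed between times: 11 of 100 drawn splits (of 200), the real one included, gave as many. The highest was 3516 in a split that follows the transcript length of the 24 h libraries, so chance is not excluded for that count.

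At 24 h, 4 of 8 libraries stood apart by transcript length, and they were 1 uninjured, 2 anti-GFP and 1 SZN-1326-p library. The split of the 6 treated mice along this line gave 2388 epithelial genes against 1095 for the treatment, and 1924 progenitor genes against 12, which points to a structure of the samples. With a term for the split the median change of called genes kept 0.939 of its size at 24 h (quartiles 0.855 to 1.02, with 1074 of 1095 genes still called). It kept 0.962 in progenitors (12 of 12) and 0.981 for DSS (2496 of 2510). The called changes were thus little altered by the term, but this cannot decide whether the split caused calls. The split divides each arm at 24 h, so that a gene driven by it varies within arms and is less likely to be called. For DSS it is also nearly even between the arms. A difference in library preparation may underlie the split: in 3 of 3 cell classes with all 8 libraries measured (epithelial, endothelial and myeloid, not the fibroblasts that define the split) every library of the split lay above every other at 24 h. The labels give no batch, and no biological explanation was tested. At 48 h the same measure separated the arms in epithelial cells (-0.058 to 0.13 with anti-GFP, -0.40 to -0.18 with SZN-1326-p). The term marks libraries at 24 h alone and does not address that.

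The changes in epithelial cells came with a changed makeup of cell types. At 24 h a shift in makeup is argued against as the whole cause, since with fixed weights for 9 types the median called gene kept 0.701 of its change (quartiles 0.542 to 0.874), although 1 gene passed the test in that fit of 6 mice (0 in a fit of the same mice without weights, 1095 in the fit of 16) and the weights leave out StemCell and TA2 (TA2 went from 7.19% to 24.9%). At 48 h it kept 0.499 (quartiles 0.316 to 0.677), and makeup and change within types cannot be told apart there, because that median lies between the bounds set for each and the weights cover 8 types without tuft cells. Within AltEnteroPC, Axin2 and Rnf43 were higher and Fzd5 lower in 6 of 6 mice, but these genes were chosen after the data were seen and had been called in the whole epithelium of the same mice, so this decides nothing; in other types Axin2 was 0.0804 against 0 in AltEnterocyte2, 0.277 against 0 in StemCell, 0.0903 against 0.0904 in BasalGoblet and 0.112 against 0.101 in TA2, and Rnf43 0.208 against 0.0768 in BasalGoblet and 0.315 against 0.437 in TA1. How much of the result the makeup accounts for stays open.

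Transcripts of enteroendocrine cells were higher outside the epithelium at 48 h. In T lymphoid cells free RNA is argued against for most of the Gcg UMIs, since 2 of 156 cells held 92.9% of them (336, with 24 elsewhere). Enteroendocrine cells placed among the T cells are a candidate explanation, with 0 T cell marker UMIs in those 2 cells where 7.20 were expected. These cells held 218 and 94 UMIs of Gcg, 139 and 103 of Insl5 and 143 and 131 of Pyy among 1558 and 1011. Without them T lymphoid cells were still higher in 8 epithelial transcripts that were called higher in fibroblasts. Their summed level was 434, 245 and 554 CPM in the SZN-1326-p mice and 70.8, 144 and 132 in the anti-GFP mice at 48 h. For this remaining rise free RNA stays open. In fibroblasts doublets confined to 1% of the cells are argued against, since the top 1% (15 of 1469) held 9.17% of the UMIs of 8 such genes. Doublets spread over more of the fibroblasts cannot be excluded by this test, since their UMIs would not gather in the top 1%. Free RNA also stays open, since levels in the other classes were 1.19 to 2.44 times those in fibroblasts of the same mouse (myeloid and endothelial up to 1.69, T lymphoid without the 2 cells 2.03 to 2.24, B or plasma 1.54 to 2.44) and the highest lies between the bounds set for and against it. The most abundant epithelial genes rose by less, with Krt8 at 113 ± 64.7 CPM against 40.2 ± 14.8, Epcam at 62.0 ± 45.4 against 13.1 ± 8.05 and Lypd8 at 46.6 ± 38.2 against 27.3 ± 5.68, while Gcg was at 16.1 ± 11.1 against 0.923 ± 0.509 and Pyy at 26.4 ± 18.7 against 0.932 ± 0.921 (SD, n = 3) with epithelial levels of 221 against 224 and 275 against 281, a mismatch that free RNA in the proportions of the whole epithelium leaves unexplained, and the labels name a FACS step but no gate that would remove epithelial cells.

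Other splits of the mice were counted for the remaining results, and each number of splits below includes the real one. For all epithelial cells, 1 of 100 drawn splits (of 200) gave as many genes as SZN-1326-p over both times (3038, highest other 747) and 1 of 100 as many as DSS (2510, highest other 1411). This makes chance unlikely for both, as for DSS in fibroblasts (1 of 100, with 2497 genes and a highest other of 1311). In each case 1 of 100 is the smallest share possible. For comparisons of 3 against 3 mice the 10 splits are too few for a share under 0.05. As many genes as the real split came from 2 of 10 splits for epithelial cells at 24 h and 1 of 10 at 48 h (1345, highest other 2), from 2 of 10 for progenitors at 24 h and 1 of 10 at 48 h (36, highest other 0). At 48 h the numbers were 1 of 10 for fibroblasts (13, highest other 1), T lymphoid cells (3, highest other 1) and myeloid cells (2, highest other 0) and 4 of 10 for B or plasma cells (1, highest other 1). As many lists came from 9 of 10 splits in epithelial cells at 24 h (7, highest other 20), 8 of 10 at 48 h (9, highest other 15), 10 of 10 in progenitors at 24 h (4, highest other 15) and 2 of 10 at 48 h (12, highest other 12). For DSS 16 of 100 splits gave as many lists in epithelial cells (14, highest other 20) and 17 of 100 in progenitors (14, highest other 17), so chance is not excluded for these counts of lists.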

How the results depend on the processing

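Planned and added alternatives (the added ones, chosen after seeing the data, are voom, mean log2, median-of-ratios scaling, a pseudocount of 0.05, the smaller set without high mitochondrial shares, fixed makeup, the library term and every setting of the compartment shares) left most results where they were. For single genes 5064 of 5892 values counted as unchanged, 509 fell below the threshold, 126 passed it, 16 reversed and 177 moved without a test. For lists 695 of 812 counted as unchanged, with 103 below and 14 past it. For shares of single types and progenitors these were 1280 of 1410, with 118 below, 9 past it and 3 reversed. A result past the threshold counted as unchanged if it kept direction and side. One not past it had only to stay so, and for genes to lie within the standard error of its main value. Changes of sign among results that stayed below the threshold are therefore not among those reversed. Of 425 values of counts, compartment shares and correlations 294 stayed within the bound, 6 fell below the threshold, 124 moved and 1 reversed. For counts the bound was 1.5-fold of the main value in either direction. Count models with other size factors and random draws to an equal makeup were not run. Unless stated, the cause was not tested; fits of the compared groups alone, fits with fixed makeup (made on the compared groups alone, with some types left out) and left-out mice use fewer samples, and an arm left with few mice is assumed to vary like the other groups.

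For SZN-1326-p in epithelial cells at 24 h (1095 genes) the count was 0 with only the groups compared, 2202 with voom, 1694 with the library term, 360 without both mice of high mitochondrial share and 1 with fixed makeup in the same 6 mice that gave 0. At 48 h (1345) it was 2556 with the library term, 812 without those mice, 1880 with only the groups compared and 237 with fixed makeup in those 6 mice. Over both times (3038) it was 2774 with only the groups compared and 228 with fixed makeup in those 12 mice. For the difference between times (15) it was 1 with no filter, 6 with only the groups compared, 5 with median-of-ratios scaling, 25 with mean log2, 0 with voom, 60 with the library term, 0 without the mice of high mitochondrial share, 46 without cells with 2 markers of another lineage and 1 with fixed makeup. For DSS (2510) it was 2164 with only the groups compared and 569 with fixed makeup in those 10 mice.

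In progenitors at 24 h (12) the count was 0 with no filter, 0 with only the groups compared, 27 with mean log2, 113 with voom, 94 with the library term and 0 without the mice of high mitochondrial share. At 48 h (36) it was 12 with no filter, 65 with only the groups compared, 73 with mean log2, 152 with the library term and 0 without those mice. At 48 h fibroblasts (13) gave 2 with voom, 39 with a replicate block, 109 with the library term and 2 without those mice. Endothelial cells (0) gave 5 with voom, 2 with a replicate block, 2 with the library term and 22 with at least 50 cells per library. B or plasma cells (1) gave 15 with voom and 0 with the library term. Myeloid cells (2) gave 32 with voom, 13 with a replicate block, 0 without those mice and 4 with at least 50 cells, which gave 1 at 24 h. Of same-numbered pairs of mice 4 of 6 correlated above 0.1 (r -0.30 to 0.44), and of other pairs 2 of 12 (r -0.62 to 0.41), so that pairing by replicate number is neither shown nor excluded.

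The correlation of SZN-1326-p with DSS effects at 24 h (-0.14) was -0.062 over genes past the threshold for DSS, 0.071 (reversed) across times with no shared library and -0.089 with the library term; at 48 h it was -0.18 across times. With an estimated correlation 1 list passed for SZN-1326-p in epithelial cells at 24 h and 0 at 48 h, 0 for DSS and 0 in the 3 progenitor comparisons; fry gave 0 in progenitors at 24 h, 0 at 48 h and 8 for DSS. The 2 shares past the threshold for SZN-1326-p became 0 with a replicate block and 0 without the mice of high mitochondrial share. Both settings leave fewer arrangements of the mice, so that 2 types alone could not pass adjustment there whatever their difference. These losses therefore say nothing about the 2 types. The epithelial share of all cells (log2 0.565, exact permutation p = 0.025) stood at 0.565 (permutation p = 0.125) with a replicate block and 0.354 (permutation p = 0.09) without those mice.

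With fixed makeup (for DSS, 5 types with no mature or immature enterocytes) the named genes that reversed included Stat2 to 0.041 and Vegfa to 0.16 with SZN-1326-p at 48 h and, with DSS, Mal to 1.79, Krt20 to 1.10, Car1 to 1.11, Slc26a3 to 0.77, Uhrf1 to -0.030, Mcm2 to -0.30, Nolc1 to -0.14, Mep1a to 0.45, Adm to 1.01, Ankrd37 to 0.71, Pkm to 0.20, Gapdh to 0.12 and Mdm2 to 0.18. As a share of all cells, Macrophage reversed to 0.166, Tcell2 to 2.05 and the pooled progenitors to -0.600 for DSS.

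Leaving out single mice gave 275 to 1880 genes for epithelial cells at 24 h, 590 to 1147 at 48 h, 2065 to 3646 over both times, 0 to 21 for the difference and 1028 to 2980 for DSS; 0 to 629 in progenitors at 24 h and 6 to 41 at 48 h. It gave 0 to 0 for fibroblasts and for endothelial cells at 24 h, 4 to 17 and 0 to 3 at 48 h, 0 to 1 and 2 to 6 for T lymphoid cells, 0 to 6 for B or plasma cells at 48 h, and 0 to 1 and 0 to 21 for myeloid cells. The correlations ranged from -0.305 to -0.0838 at 24 h, -0.362 to -0.235 at 48 h and -0.229 to -0.146 over both times, the epithelial shift of SZN-1326-p from 0.428 to 0.638 log2, and shares past the threshold from 0 to 3 for SZN-1326-p and 6 to 13 for DSS. Genes of low level were recovered less often. Of simulated 2-fold changes in epithelial cells at 48 h the test recovered 13 of 36 among genes below the median level (0.232 normalized UMIs per cell) and 22 of 31 among the others. This division was chosen after the data were seen, and the simulated genes varied independently of each other. Depth was not varied, so its part in this was not tested.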

Other observations

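The tests of fibroblasts under DSS and of heat shock levels were chosen after the data were seen.

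Genes measured in fibroblasts changed with DSS, inflammatory genes among them. Of 24 NF-kB and cytokine genes 18 rose and 0 fell (21 adjusted over the list alone; median 1.35, adjusted p = 1.48e-15), and the call held with an estimated correlation (adjusted p = 0.0235). Cxcl5, a neutrophil chemokine, rose from 0.00744 ± 0.00591 (SD, n = 4) to 1.54 ± 0.651 (n = 6) normalized UMIs per cell (log2 6.43, adjusted p = 7.95e-10 in limma), and the cytokines Il11 and Il6 rose by 4.29 (adjusted p = 0.00125) and 2.75 (adjusted p = 0.00042). Of 31 interferon genes 20 rose (24 adjusted over the list alone; median 0.91, adjusted p = 9.82e-14, adjusted p = 0.207 with an estimated correlation). Of 26 matrix genes 10 rose and 2 fell (12 and 4 adjusted over the list alone; adjusted p = 0.00161, adjusted p = 0.221 with an estimated correlation), with the matrix metalloproteinases Mmp3 and Mmp13 at 3.71 (adjusted p = 2.64e-05) and 5.28 (adjusted p = 0.00752). All 6 anti-GFP mice showed the direction of each of these 5 genes. In all, limma called 2497 of 11112 genes, 1373 higher and 1124 lower, and 3466 with the library term. RNA of other cell types moved along in the same fibroblasts: 4 of 7 neutrophil and monocyte genes rose (4 adjusted over the list alone; median 0.99, adjusted p = 0.0207, adjusted p = 0.221 with an estimated correlation), while 17 of 27 colonocyte genes fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 1.27e-08, adjusted p = 0.265 with an estimated correlation). Lower were also 6 of 16 goblet genes (6 adjusted over the list alone; adjusted p = 0.00286, adjusted p = 0.511 with an estimated correlation) and 2 of 6 lymphocyte and plasma cell genes (3 adjusted over the list alone; adjusted p = 0.0348, adjusted p = 0.511 with an estimated correlation).

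Fibroblast genes of the Wnt niche moved both ways with DSS, across groups that hold different fibroblast types (BaseCryptFB1 went from 42.9% of stromal cells to 0, InjuryCryptFB1 from 0.0735% to 8.39% and InjuryCryptFB2 from 1.69% to 19.3%). Of 15 Wnt ligands, R-spondins and inhibitors 7 rose and 5 fell (7 and 5 adjusted over the list alone; median 0.55), and the list did not pass (adjusted p = 0.073). Wnt5a, a non-canonical ligand, rose from 0.785 ± 0.0338 (SD, n = 4) to 2.25 ± 0.398 (n = 6; log2 1.49 ± 0.15, adjusted p = 6.17e-07), Grem1, a BMP antagonist, from 1.52 ± 0.369 to 6.08 ± 0.919 (log2 2.01, adjusted p = 1.8e-08) and the R-spondin Rspo1 from 0.0872 ± 0.0142 to 0.359 ± 0.188 (log2 1.80, adjusted p = 0.000545). The secreted inhibitors Sfrp1 (1.11, adjusted p = 4.04e-05) and Sfrp2 (2.63, adjusted p = 5.94e-05) rose, while the ligands Wnt2b (-0.68, adjusted p = 0.0391) and Wnt6 (-1.24, adjusted p = 0.0069) and the inhibitor Dkk3 (-0.56, adjusted p = 0.006) fell. All 6 anti-GFP mice showed the direction of each of these 8 genes.

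The heat shock gene Hspa1b measured 1116 ± 463 CPM (SD, n = 3) in endothelial cells of anti-GFP mice at 48 h, against 188 ± 18.2 with SZN-1326-p and 195 ± 114 in 2 uninjured mice, and 320 ± 122 against 74.0 ± 26.9 in epithelial cells. In fibroblasts it was 464 ± 179 with anti-GFP against 118 ± 25.7 with SZN-1326-p. Myeloid cells showed no such peak, with 94.4 ± 12.2 for anti-GFP, 58.4 ± 18.4 for SZN-1326-p and 103 ± 57.45 in uninjured mice. In limma the endothelial difference did not pass (log2 -2.41, adjusted p = 0.0814) and the epithelial one did (log2 -2.21, adjusted p = 0.000734). At 24 h the order of Hspa1b was the other way, with 164 ± 33.5 for SZN-1326-p against 117 ± 68.1 in endothelial cells and 79.6 ± 32.9 against 38.1 ± 7.60 in epithelial cells.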
